A study of Mus musculus with 6 samples.

How the data were processed

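Total RNA of the mouse mammary tumour cell line 4TO7 was measured on 6 arrays, 3 from cells that carried the empty pcDNA vector (control) and 3 from cells with Six2 overexpression (Six2). The groups and replicate numbers came from the sample labels. Biotin-labelled cRNA was prepared from 6 ug of total RNA, per the labels' protocols. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical. No hybridisation or scan dates were used here, so a batch that follows the groups cannot be told apart from the group.

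The authors deposited log2 values made with Affymetrix Power Tools and RMA, per the submitters' processing notes, a method that corrects the background, quantile-normalizes and summarises probe intensities. Versions, the probe set filter and the genome build are not given in the sources used here. The table held 241576 rows, each a probe set, most of them covering a part of a gene. RMA makes the value distributions of the arrays alike, so a change in the total amount of RNA per cell is not visible in such values, and it compresses folds of dim genes. The table carries no detection calls. For arrays, their number limits the precision, here 3 per group.

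Gene names came from the platform annotation. Of the rows, 213361 had 1 gene symbol, 5107 had several and 23108 had none. Of 20893 symbols, 18496 were in the RefSeq gene table (assembly GRCm38.p6) as given, 2354 were replaced through a synonym and 43 were not found. This table was used for names, chromosomes and gene span, and for gene positions, which gave gene density and which genes neighbour each other. No coordinates are given since the array build was not stated. The value of a gene was the median over its probe sets with that symbol alone, with a median of 8 probe sets per gene and 2636 genes with 1. This gave 20848 genes, and no filter on dim genes was applied.

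Groups were compared with limma 3.58.1 (lmFit and eBayes, without trend or robust variance) in R 4.3.3 with the data.table package, version 1.17.8. Calls used a two-sided Benjamini-Hochberg adjusted p under 0.05 over all genes. Signed values are Six2 minus control on the log2 scale, SE is the moderated standard error, and SD is over 3 arrays. Six2 and Cdh1 also had an exact two-sided permutation test, whose smallest possible p with 3 against 3 arrays is 0.1. The same limma test was run on each probe set. Unequal change among the probe sets of a gene was tested with diffSplice and Simes p-values.

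Gene lists were fixed before the data were examined. There were 47, of which 17 fitted the study, 19 were general pathways and 11 were markers of cell types. They were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists. With an estimated correlation, camera has less power with so few arrays, so a call lost there need not come from correlated genes. The named genes followed a rule also fixed before the data were examined. It took Six2 and Cdh1, changed members of the EMT transcription factor and Six2 network lists, and the 12 largest rises and 12 largest falls among changed genes whose groups did not overlap, without predicted genes. It also took up to 4 members with the smallest p per direction from each list that fitted the study, passed camera or held at least 3 changed members. Chance separates 3 against 3 arrays in 10% of genes.

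The steps were tested on simulated data with the means and residual SDs of the real genes or probe sets. In 3 against 3 simulated arrays with 20848 genes, limma recovered 16.4% of 67 genes changed by 0.5 on the log2 scale, 65.7% of 67 changed by 1 and 86.4% of 66 changed by 2. Of its calls, 4.10% were unchanged genes. Only 220 of the simulated genes were changed, so these rates need not hold where many more genes change. In a simulation of 3000 genes, of which 200 had 1 probe set raised by 2, diffSplice recovered 92.0% of the changed genes, but 58.6% of its calls were unchanged genes. It assumes a common variance for the probe sets of a gene, while the simulation gave each probe set its own estimated residual SD. Such estimates from few arrays scatter even where true variances are equal, so the simulation may overstate the false calls. Whether variances differ in the real data was not tested. A test that gives each probe set its own variance was added after these false calls were seen. It takes a probe set minus the mean of the other probe sets of its gene, fits limma and combines p-values per gene by Simes. It recovered 60.5% of the 200 genes, and 2.42% of its calls were unchanged genes.

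Alternatives set before the data were examined were the mean or the brightest probe set per gene, leaving out rows at or below the 30th percentile of mean value, quantile normalization, centring of arrays, a replicate block, leaving out each array, a variance trend with robust variance, no moderation, array weights, an adjusted p under 0.01 and a 2-fold limit. Added after the data were seen were the subtraction of chromosome medians, the removal of genes on chromosomes 1, 3 and 17, the unequal probe set tests on bright probe sets and with separate variances, and the epithelial list without Cdh1. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.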

Results

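Gene expression was compared between 4TO7 cells with Six2 overexpression and cells with the empty vector, 3 arrays each. 4TO7 is a mouse mammary tumour line, and Six2 is a homeobox transcription factor known for keeping nephron progenitors undifferentiated. The series title links Six2 to the control of E-cadherin, so the comparison asks how Cdh1 and other genes differ between the groups. Pearson correlations over genes were 0.994 within the control group, 0.992 to 0.994 within the Six2 group and 0.983 to 0.987 between groups. These are across genes, which are not independent replicates. The first principal component held 55.0% of the variance and separated the groups, and the next held 15.2% and set Six2 replicate 3 apart.

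Six2 itself was dim in both groups, at 3.52 ± 0.23 (SD, n = 3) in control arrays and 3.86 ± 0.23 (SD, n = 3) in Six2 arrays. The difference of 0.33 (SE 0.16) did not pass (limma adjusted p = 0.215, exact permutation p = 0.3). Its 4 probe sets moved apart, from -0.60 to 1.19, and none passed over all rows. The probe set 10453397 averaged 3.59 in control and 4.78 in Six2 arrays, and 10453395 averaged 3.45 and 4.25. In both, every Six2 array lay above every control array. In 10453398, which averaged 4.08 and 3.48, every Six2 array lay below every control array. The gene passed in 3 alternatives: with the mean of the probe sets (0.38, limma adjusted p = 0.0242), with its brightest probe set (1.19, limma adjusted p = 0.0480) and with dim rows left out (1.19, limma adjusted p = 0.0276), within a range of 0.0242 to 0.479 over all 16 alternatives. The settings with the brightest probe set and with dim rows left out both rest on 10453397 alone, so they are not separate measurements. It is the brightest over all arrays, but in control arrays 10453398 was brighter. The labels do not give the species or the extent of the Six2 insert, so these probe sets give only a weak check of the labels.

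Cdh1, which encodes the epithelial adhesion protein E-cadherin, fell 8.91-fold. Its level was 7.57 ± 0.11 (SD, n = 3) in control arrays and 4.41 ± 0.17 (SD, n = 3) in Six2 arrays, a difference of -3.16 (SE 0.12, limma adjusted p = 6.56e-05). The exact permutation p was 0.1, the smallest that 3 against 3 arrays allow. Of its 20 probe sets, 17 fell and none rose past the threshold, with differences from -4.31 to 0.87. The test of unequal change among them passed in diffSplice (adjusted p = 5.50e-13), which made many false calls on simulated data, and not with separate variances (limma adjusted p = 0.0690).

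**Figure D1:**
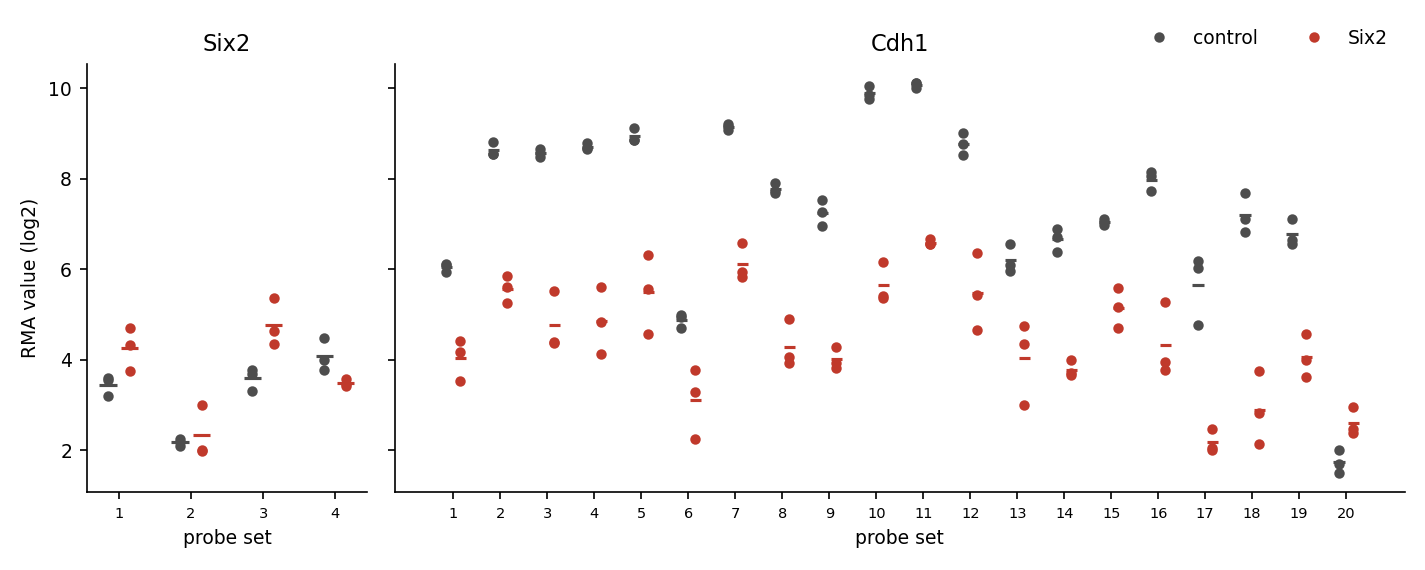
RMA values (log2) of the 4 Six2 and 20 Cdh1 probe sets on each array, with control arrays in grey, Six2 arrays in red and a bar at each group mean of 3 arrays. For Cdh1, 17 probe sets fell past the threshold, while the Six2 probe sets stay dim in both groups.

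Across all genes, 3068 of 20848 (14.7%) changed, 1396 higher and 1672 lower in Six2 arrays. Most changes were small, with 2581 under 2-fold, 187 at least 2-fold higher and 300 at least 2-fold lower. Hspb1, a small heat shock protein, rose most among the named genes, by 3.49 (SE 0.13, limma adjusted p = 6.56e-05). Other large rises were Mid2 (3.32), Tnfsf13b, the B cell survival factor BAFF (2.88), Il33, an alarmin cytokine (2.76), Pcdh18 (2.71), Hhip, a Hedgehog antagonist (2.70), Ndp, a Wnt pathway ligand (2.66), and Cd53 (2.65). Eya1 (2.48), the transcriptional coactivator Ppargc1a (2.36), the DNA sensor Aim2 (2.31) and the lipase Lipg (2.30) completed the 12 largest. With the brightest probe set, Mid2 was at 0.40 and did not pass (limma adjusted p = 0.481), and the passing values were 2.05 for Hspb1, 1.24 for Il33, 0.50 for Hhip and 1.495 for Ppargc1a. Lcn2, an iron-binding secreted protein, fell by 4.03 on the log2 scale (SE 0.14, limma adjusted p = 6.56e-05). Other large falls were Pate14 (-4.12), Mustn1 (-3.81), Ly6a (-3.78), Rassf4 (-3.46), Mcpt8 (-3.44), Masp1 (-3.23), Igfbp7 (-2.91), Selenbp1 (-2.91), the desmosomal protein Pkp1 (-2.83) and Cyp1b1 (-2.73). Pkp1 was at -1.12 with its brightest probe set, and Mustn1 and Masp1 at -2.44 and -1.83 with the mean of the probe sets, all still past the threshold. Pate14, Ly6a and Mcpt8 belong to families of similar genes, so their values are uncertain where probes match several members.

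**Figure D2:**
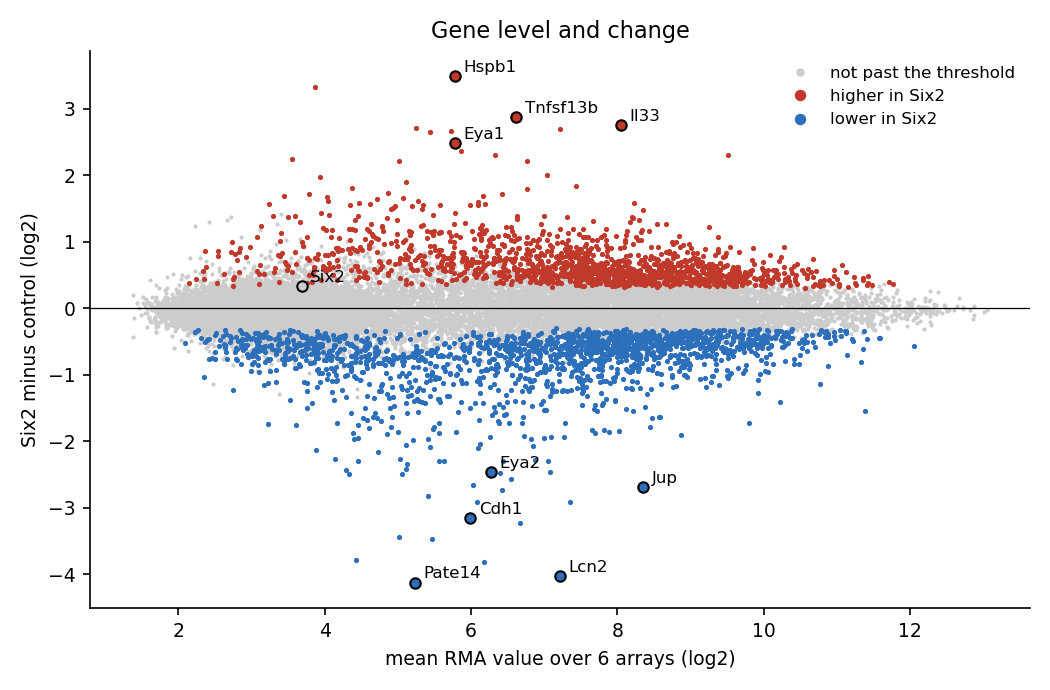
Each point is a gene, with its mean RMA value over 6 arrays (log2) on the horizontal axis and the Six2 minus control difference (log2) on the vertical axis. Red and blue mark the 1396 higher and 1672 lower genes, grey the rest, and circles the genes named beside them.

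The changes were unevenly spread over chromosomes, a pattern noticed after the data were seen. Among 8949 genes with a mean above 6, the median difference was 0.44 on chromosome 1, where 272 of 497 genes rose and 15 fell, and 0.37 on chromosome 3, where 178 of 419 rose and 13 fell. On chromosome 17 it was -0.26, and 7 of 454 genes rose and 154 fell. Smaller shifts were also seen elsewhere, among them medians of 0.22 on chromosome 12, 0.18 on chromosome 8 and 0.17 on chromosome 10. Chromosomes 16 and 19 each had a median of -0.18. The setting without chromosomes 1, 3 and 17 keeps these smaller shifts. Chromosomes 1 and 3 held 41.1% of the higher genes and 10.2% of the genes with such levels. Camera called 15 of 20 chromosomes with the preset correlation and 0 with an estimated correlation, where the adjusted p was 0.0953 for chromosome 1, 0.130 for chromosome 3 and 0.0702 for chromosome 17. Eya1, Aim2 and Pkp1 lie on chromosome 1, and Pcdh18, Cd53 and Selenbp1 on chromosome 3. Genes with a mean of at most 4 had medians of -0.06 over 477 genes on chromosome 1, -0.10 over 390 on chromosome 3 and -0.06 over 378 on chromosome 17. Such genes lie near background, where a shift could hardly show, so these medians do not bear on its cause. With chromosome medians subtracted, 2082 genes changed, 775 higher and 1307 lower. Only genes with a mean above 6 were adjusted, so Eya1, Pkp1, Pcdh18 and Cd53 were left as they were.

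**Figure D3:**
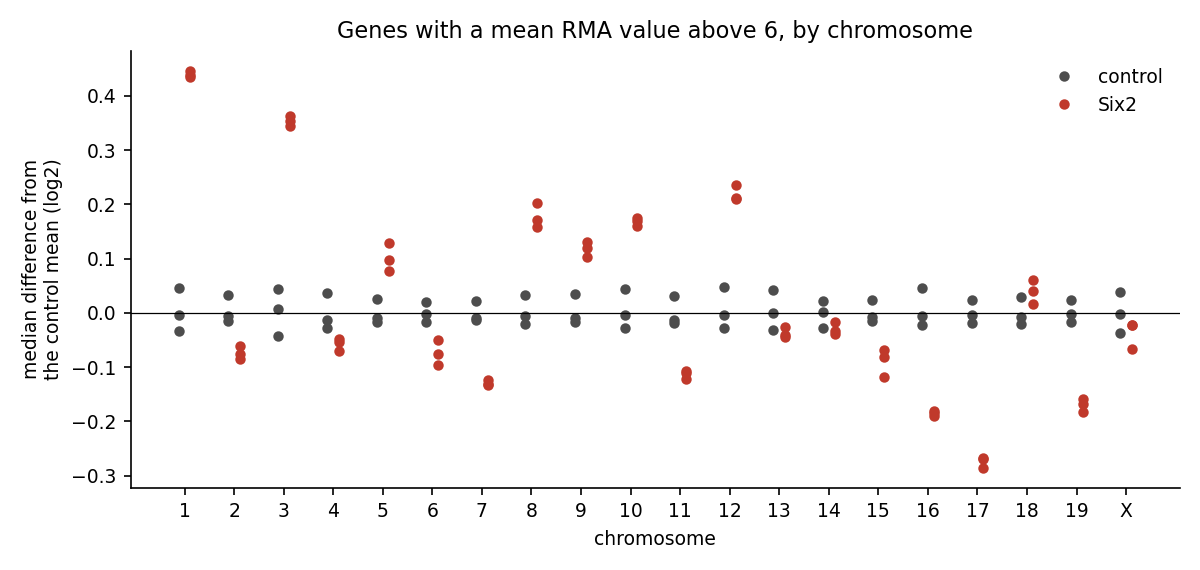
For genes with a mean RMA value above 6, the median difference of each array from the control mean (log2), by chromosome, with 3 control arrays in grey and 3 Six2 arrays in red. The Six2 arrays lie at 0.43, 0.45 and 0.44 on chromosome 1.

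Where epithelial genes changed, they were lower. Of 38 epithelial adhesion and junction genes, 0 rose, 9 fell and 29 did not pass (0 and 10 adjusted over the list alone). Beside Cdh1 these were led by Jup, which encodes plakoglobin (-2.68, SE 0.14), Pkp1 (-2.83, SE 0.18) and Lsr, a tricellular junction protein (-1.21, SE 0.12). Only 8 of the 38 genes had a control mean above 6. Genes near background in control arrays can hardly show a fall, so the 29 are not 29 genes shown to be unchanged. Camera called the list lower (adjusted p = 0.0205), but not with an estimated correlation (adjusted p = 0.464), and not without Cdh1 (adjusted p = 0.0684), which the series title names. Of 15 keratins and partners, 0 rose, 7 fell and 8 did not pass (1 and 10 adjusted over the list alone). They included Krt7 (-2.27), Perp (-1.64), Ppl (-1.20) and Krt19 (-1.24). Of the 15, 6 had a control mean above 6. Camera called this list lower (adjusted p = 0.00250), with adjusted p = 0.464 with an estimated correlation. The estimated correlations, -0.022 for the epithelial list and -0.065 for the keratins, were below the preset 0.01. The calls lost there therefore do not come from a stronger correlation among members. With dim rows left out, the adjusted p was 0.0984 for the epithelial list and 0.0599 for the keratins. The call of Lsr was lost with its brightest probe set (-0.53). The calls that held in every alternative run were 5 of the 9 epithelial falls and 6 of the 7 keratin falls.

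Where mesenchymal genes changed, most were lower. Of 32, 1 rose, 6 fell and 25 did not pass (1 and 6 adjusted over the list alone), with Tnc, which encodes tenascin C, up by 1.09 (SE 0.19), and Sparc (-0.87), Fn1, which encodes fibronectin (-0.62), and Tpm1 (-1.08) lower. The calls of Tnc (0.63) and Tpm1 (-0.20) were lost with the brightest probe set. A control mean above 6 was found for 11 of the 32 mesenchymal genes and 7 of the 16 EMT transcription factors. Among 16 EMT transcription factors, 1 rose, 2 fell and 13 did not pass (1 and 2 adjusted over the list alone). Snai1 fell by 0.68 on the log2 scale (SE 0.11, limma adjusted p = 0.00816) and Foxc1 fell by 0.68 (SE 0.15, limma adjusted p = 0.0237). Zeb2 rose by 0.41 (SE 0.10, limma adjusted p = 0.0371). The calls of Zeb2 and Foxc1 were lost in 9 and 7 of 17 alternatives, with adjusted p up to 0.112 and 0.123. Zeb2 was lost without any control array and without Six2 replicate 1 or 2 (0.33 to 0.43), and Foxc1 without control replicate 2 or 3 and without Six2 replicate 1 or 3 (-0.66 to -0.60). Foxc1 was also lost with the mean of the probe sets (-0.36) and with its brightest probe set (-0.38), where its fall was smaller. Fn1 was at -1.05 with chromosome medians subtracted. Calls held in every alternative for 0 of 1 rise and 2 of 6 falls among mesenchymal genes, and for 0 of 1 and 1 of 2 among the transcription factors. Neither list passed camera, with adjusted p = 0.389 and 0.702.

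Members of the network of Six2 relatives and their Eya, Dach and Pax partners went both ways. Of 15, 2 rose, 2 fell and 11 did not pass (2 and 2 adjusted over the list alone). Eya1, a cofactor of Six2 relatives, rose 5.57-fold (2.48, SE 0.15, limma adjusted p = 0.000324), while its relative Eya2 fell 5.51-fold (-2.46, SE 0.16, limma adjusted p = 0.000380). Six4 rose by 0.67 (SE 0.11) and Six5 fell by 0.81 (SE 0.10). A control mean above 6 was found for 4 of the 15 network genes and 3 of the 16 nephron progenitor genes. Of 16 nephron progenitor genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone), namely Eya1, Itga8 (-0.88) and Tmem100 (-0.91). Of 18 stem and progenitor cell genes, 0 rose and 2 fell (0 and 2 adjusted over the list alone), Procr (-1.29) and Aldh1a1 (-0.43). The call of Aldh1a1 was lost in 12 of 17 alternatives, and in 1 of these, with dim rows left out, its sign turned (0.16). The 4 calls of the network and the 3 of the nephron list held in every alternative run on them, though Eya2 was at -1.63 with its brightest probe set. Neither chromosome setting tested Eya1, since its mean lies under 6 and the removal of chromosome 1 drops it.

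**Figure D4:**
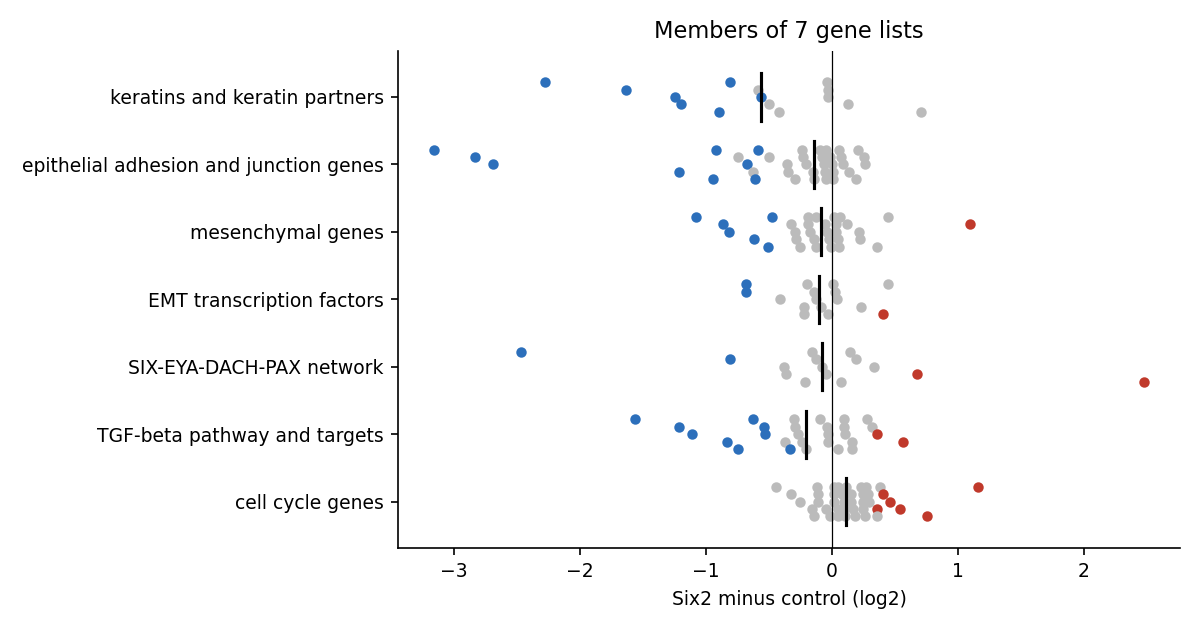
Members of 7 gene lists by their Six2 minus control difference (log2), with a black bar at each list's median, red and blue for members that rose or fell past the threshold and grey for the rest. In the epithelial adhesion list 9 of 38 members fell and 0 rose.

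Of 17 DNA methylation genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone), the demethylase Tet2 (1.35, SE 0.14) and the methyltransferase Dnmt3b (0.74, SE 0.11). Dnmt3b was at -0.34 by its brightest probe set, and Tet2 held in every alternative. Of 27 Polycomb and histone deacetylase genes, 2 rose and 2 fell (2 and 3 adjusted over the list alone), with Rnf2 (0.49) and Ezh2 (0.41) higher and Cbx7 (-0.35) and Ring1 (-0.54) lower. These calls were lost in 10 of 17 alternatives for Cbx7, 10 of 16 for Ring1, 7 of 17 for Ezh2 and 1 of 16 for Rnf2, which was at 0.054 with chromosome medians subtracted (limma adjusted p = 0.739).

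Where collagen and matrix genes changed, they were lower. Of 35 collagen and matrix genes, 0 rose and 7 fell (0 and 7 adjusted over the list alone), among them Lama4 (-2.05), Fbln2 (-1.36), Lox (-1.11) and Thbs1 (-1.02). Of 16 integrins, 2 rose and 4 fell (2 and 5 adjusted over the list alone), with Itgb3 (-2.46) and Itgb4 (-1.25) lower and Itga2 (1.16) and Itga7 (1.17) higher. Of 28 extracellular proteases and inhibitors, 4 rose and 4 fell (4 and 5 adjusted over the list alone). Mmp10 (1.48) and Adam8 (1.22) rose, and the protease inhibitor Timp3 (-2.49) and the plasminogen activator Plat (-1.31) fell. None of these 3 lists passed camera, with adjusted p = 0.327, 0.715 and 0.644. With the brightest probe set, the calls of Fbln2 (-0.11), Lama4 (-1.18), Lox (-0.84), Itga7 (0.76) and Plat (-0.93) were lost. The call of Lox was lost in 2 of 17 alternatives, with its smallest fall at -0.63, and the lowest value of Itga7 was 0.56. Among the integrin falls, that of Itga3 was lost in 11 of 17 alternatives and that of Itgb7 in 6 of 17. In every alternative, 2 of 7 matrix falls held, 1 of 2 rises and 2 of 4 falls among integrins, and 3 of 4 rises and 2 of 4 falls among proteases and inhibitors.

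Several signalling lists had more falls than rises, and none of them passed camera (adjusted p = 0.0877 for Wnt, 0.134 for TGF-beta). Of 29 TGF-beta pathway genes, 2 rose and 9 fell (4 and 11 adjusted over the list alone), with Smad3 (-0.83), Inhba (-1.21) and Fst (-1.56) lower and Pmepa1 (0.57) higher. Of 28 Wnt genes, 1 rose and 5 fell (1 and 5 adjusted over the list alone), with Notum (-1.09) and Sfrp1 (-0.86) lower and Wnt7b (1.19) higher. Of 16 Notch pathway genes, 2 rose and 5 fell (2 and 6 adjusted over the list alone), with the targets Nrarp (-1.78) and Hes1 (-0.60) lower and the ligand Dll4 (0.63) higher. Of 16 YAP targets, 1 rose and 5 fell (3 and 5 adjusted over the list alone), including Ccn2 (-1.11) and Dusp1 (-1.20). Of 22 angiogenesis factors, 5 rose and 8 fell (6 and 10 adjusted over the list alone), with Sema3a (1.55) and Angptl4 (1.20) higher and Nrp1 (-1.43) and Pdgfb (-1.32) lower. The calls of Sema3a and Pdgfb were lost without variance moderation. With the brightest probe set, values were 0.58 for Sema3a, 2.42 for Angptl4, -0.92 for Fst and -0.99 for Hes1, all past the threshold. The rises and falls that held in every alternative were 1 of 2 and 6 of 9 for TGF-beta, 1 of 1 and 2 of 5 for Wnt, 1 of 2 and 4 of 5 for Notch, 0 of 1 and 3 of 5 for YAP targets, and 1 of 5 and 1 of 8 for angiogenesis factors.

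Where cell cycle genes changed, they were higher. Of 41, 6 rose, 0 fell and 35 did not pass (6 and 0 adjusted over the list alone), with Cenpf (1.16, SE 0.16), Cenpe (0.76, SE 0.14), Ccne2 (0.54, SE 0.11) and Ccna2 (0.36, SE 0.08) among them. Camera called the list higher (adjusted p = 0.00858), with adjusted p = 0.542 with an estimated correlation. That correlation was 0.098, above the preset 0.01. Cenpf lies on chromosome 1 and Cenpe and Ccna2 on chromosome 3, where the medians were 0.44 and 0.37. Camera still called the list with chromosome medians subtracted (adjusted p = 0.00949) and without chromosomes 1, 3 and 17 (adjusted p = 0.0323). Of 15 heat shock genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone), Hspb1, Hspd1 (0.42) and Hspe1 (1.03), the last 2 on chromosome 1. Of 31 oxidative phosphorylation genes, 3 rose and 2 fell (5 and 2 adjusted over the list alone), with Ndufs1 (0.71) and Sdhc (0.49), both on chromosome 1, higher and Ndufv1 (-0.43) lower. With chromosome medians subtracted, the differences were 0.39 for Cenpe, -0.012 for Ccna2, -0.019 for Hspd1, 0.59 for Hspe1, 0.27 for Ndufs1, 0.050 for Sdhc and -0.25 for Ndufv1, and none of these passed. Over all alternatives, calls were lost in 6 of 17 for Ccne2, 8 of 16 for Ccna2, 6 of 16 for Hspd1, 6 of 16 for Hspe1, 5 of 16 for Sdhc and 7 of 17 for Ndufv1. The calls that held in every alternative were 1 of 6 in the cell cycle list, 1 of 3 in the heat shock list and 0 of 5 in the oxidative phosphorylation list. Cenpf held, at 0.72 with chromosome medians subtracted.

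Stress and metabolic lists did not pass camera, but held changed members. Of 28 unfolded protein response genes, 1 rose and 8 fell (1 and 8 adjusted over the list alone), with Chac1 (-1.14) and Trib3 (-1.01) lower and Ddit3 (0.57) higher. Of 27 oxidative stress genes, 3 rose and 7 fell (5 and 8 adjusted over the list alone), with Gsta4 (-1.91), Mgst1 (-1.49) and Slc7a11 (-0.92) lower and Hmox1 (0.64) higher. Of 36 hypoxia and glycolysis genes, 2 rose and 5 fell (4 and 6 adjusted over the list alone), including Car9 (1.53) and Pfkm (-0.73). Of 28 cholesterol and fatty acid synthesis genes, 2 rose and 6 fell (5 and 8 adjusted over the list alone), with Hsd17b7 (0.81) higher and Scd1 (-0.70) lower. Of 23 p53 targets, 2 rose and 4 fell (4 and 5 adjusted over the list alone), including Mdm2 (0.58) and Plk2 (-1.09). Of 20 apoptosis genes, 1 rose and 3 fell (2 and 5 adjusted over the list alone), with Bid (-1.21) and Casp9 (-0.64) lower and Mcl1 (0.52) higher. Calls were lost in 8 of 17 alternatives for Ddit3, 7 of 17 for Mdm2 and 7 of 16 for Mcl1, 2 of 17 for Car9 and 1 of 17 for Chac1, and with the brightest probe set for Casp9 (-0.28). Mcl1 was at 0.15 in the alternative where it was lowest, and its limma adjusted p reached 0.448. Hsd17b7 passed at 0.37 with chromosome medians subtracted, and Trib3 at -1.57 with its brightest probe set. Rises and falls held in every alternative for 0 of 1 and 3 of 8 unfolded protein response genes, 1 of 3 and 5 of 7 oxidative stress genes, 0 of 2 and 1 of 5 hypoxia and glycolysis genes, 1 of 2 and 1 of 6 cholesterol and fatty acid genes, 0 of 2 and 2 of 4 p53 targets, and 0 of 1 and 2 of 3 apoptosis genes.

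Inflammatory and growth signalling genes went both ways. Of 30 cytokines and chemokines, 5 rose and 7 fell (5 and 10 adjusted over the list alone), with Il33 (2.76) and Il11 (0.92) higher and Lcn2 (-4.03), Tnf (-1.11) and Cxcl16 (-1.12) lower. Of 16 NF-kB regulators, 4 rose and 2 fell (5 and 4 adjusted over the list alone), including Nfkbia (0.73), Vcam1 (1.38) and Nfkbib (-0.51). Of 34 interferon response genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone), including Ifih1 (1.18) and Ifi35 (-0.77). Of 17 antigen presentation genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone), with Nlrc5 at 0.63 and Tapbp at -0.92. Of 33 growth factor receptor signalling genes, 5 rose and 8 fell (5 and 11 adjusted over the list alone), with Btc (2.01) and Hbegf (0.89), both EGF receptor ligands, higher and Igfbp7 (-2.91) and Spry1 (-0.86) lower. Of 24 immediate early genes, 2 rose and 7 fell (4 and 8 adjusted over the list alone), including Fosl1 (0.64) and Jund (-0.99). Of 30 cytoskeleton and motility genes, 2 rose and 4 fell (2 and 5 adjusted over the list alone), including Arpc2 (0.58) and Ezr (-0.70). With the brightest probe set, the calls of Ifih1 (0.69), Ifi35 (-0.56), Nlrc5 (0.54), Nfkbib (-0.41) and Arpc2 (0.28) were lost, and Nfkbia was at 1.20. Ezr was at -0.44 with chromosome medians subtracted. The call of Arpc2, which lies on chromosome 1, was lost in 2 of 16 alternatives, with its lowest value at 0.14. None of the 6 interferon response calls held in every alternative. Rises and falls that did were 2 of 5 and 4 of 7 for cytokines, 2 of 4 and 0 of 2 for NF-kB regulators, 0 of 1 and 1 of 2 for antigen presentation, 4 of 5 and 2 of 8 for growth factor signalling, 1 of 2 and 4 of 7 for immediate early genes, and 0 of 2 and 2 of 4 for the cytoskeleton. Among 30 ribosomal proteins 0 rose and 1 fell, among 31 Hox genes 0 rose and 2 fell, and among 17 imprinted genes 0 rose and 0 fell (0 and 0 adjusted over the list alone in each of these 3 lists). None of the ribosomal and Hox calls held in every alternative.

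Lists of cell type markers did not pass camera. Since 4TO7 is a mammary tumour line, luminal and basal mammary markers can belong to the measured cells themselves. Of 15 luminal mammary markers, 1 rose and 3 fell (1 and 3 adjusted over the list alone), the milk protein gene Csn3 (1.06) and the keratins Krt19, Krt18 (-0.81) and Krt8 (-0.56), which the keratin list also holds. Of 18 macrophage and monocyte markers, 0 rose and 4 fell (0 and 4 adjusted over the list alone), led by Cd14 (-1.85), the 1 of these 4 that held in every alternative. The calls were lost in 13 of 16 alternatives for Ptprc, 7 of 16 for Fcgr3 and 6 of 16 for Adgre1. Of 16 fibroblast markers, 0 rose and 3 fell (0 and 4 adjusted over the list alone), Gsn (-1.16), Pi16 (-1.49) and Lum (-0.48). The call of Pi16 was lost with its brightest probe set (-0.83) and that of Lum in 6 of 16 alternatives, while Gsn held in every alternative. Csn3 did too, at 1.67 with dim rows left out, and Krt8 was lost with its brightest probe set (-0.42). Adjusted over the list alone in parentheses, 1 of 12 basal mammary markers rose and 0 fell (2 and 0), 1 of 12 neutrophil markers rose and 0 fell (1 and 0), 1 of 10 B cell markers rose and 1 fell (1 and 5), and 1 of 15 skeletal muscle markers rose and 0 fell (0 and 0). None of these 5 calls held in every alternative. No member changed among 16 T and NK cell, 15 endothelial, 11 adipocyte and 6 erythroid markers (0 and 0 adjusted over the list alone in each).

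Over the 47 lists, camera called 3 with the preset correlation and 0 with an estimated correlation. Fry, which does not compare a list with other genes, called 30 lists moving on balance in 1 direction and 42 changing in either direction. At the level of single probe sets, 6756 of 241576 changed, 2887 higher and 3869 lower, and limma called 0 when any control array was left out, with 40442 to 47918 at an unadjusted p under 0.05. Genes whose probe sets changed unequally numbered 2566 of 18212 in diffSplice. That count cannot be read as a measure of such genes, since 58.6% of diffSplice calls were unchanged genes in data simulated with a separate SD for each probe set. With separate variances, limma called 0 of 18212, with 2822 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0690.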

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

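The swap test, the test of unequal Six2 probe sets, and the tests of strongly changed genes, copy number and the protocadherins' chromosome and neighbours were chosen after the results they measure were seen. Rows outside the gene test also carried a signal. Among 5107 probe sets with several gene symbols, 46 were higher and 148 lower in Six2 arrays than in control arrays. Among 23108 with no symbol, 294 were higher and 154 lower. The largest rises among them were 3.70 for 10520317 and 3.55 for 10344523, and the largest falls were -5.59 for 10429577 and -5.02 for 10429571, both with several symbols.

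Chromosome-wide shifts were the pattern most apart from single genes. The median on chromosome 1 was 0.44 among genes with a mean above 6, and the highest on any chromosome in the other 9 splits was 0.18, but 10 splits of 6 arrays are too few for a share under 0.05 (1 split reached the real value). Each of the other splits also mixes arrays of both groups, so part of a real group difference stays in it. After adjustment for gene span, gene density and level the median was 0.39, which argues against such a trend as the whole cause. Of the chromosome 1 genes with a mean above 6, 91.3% were above 0. This share argues against a few strong genes, as a median over many genes does by itself. The lowest median among 19 blocks of at least 25 neighbouring genes of chromosome 1 with such means, over the 3 Six2 arrays, was 0.26. Blocks of chromosomes 3 and 17 came closer to 0, with a lowest of 0.11 on chromosome 3 and a highest of -0.06 on chromosome 17. On chromosome 16 the block medians of the group difference ran from -0.40 to 0.0086, so that shift did not cover the whole chromosome evenly. For chromosome 1, a candidate explanation is a difference in DNA copy number between the cells of the groups, which was not measured. An effect of Six2 on these genes stays open and was not tested apart from it.

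Six2 probe sets stayed dim in both groups. The number of arrays that correlated better with an array of the other group than with their own was 0, which argues against a swap between 1 control and 1 Six2 array. An exchange of the labels of whole groups would leave this count at 0 and was not tested. The probe sets may differ in their change, as they would if the insert lacked part of the gene, but the 2 tests parted: diffSplice gave an adjusted p of 0.0257 for Six2, and the test with separate variances gave 0.206. Since diffSplice made many false calls on simulated data, this explanation stays open.

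Clustered protocadherins rose in part. Of 55, 14 rose and 0 fell, and their median was 0.25 against 0.05 in 223 other bright genes of chromosome 18, a difference of 0.20. Its lowest value in a Six2 array was 0.15 and its highest in a control array 0.032. By itself this gap fell between the limits set for and against a shift of the whole chromosome, so it does not decide on one. It also sets members with a median level of 3.59 against genes with one of 8.20. Only 3 of the 55 had a mean above 6. Of these, Pcdhgb1 rose by 1.27, while Pcdhgc5 (0.36) and Pcdhgc3 (-0.51) did not pass. The 36 other bright genes within 2 Mb of the cluster had a median of -0.11, which argues against a shift of the bright neighbourhood as the whole cause. Probes shared among these similar genes could make members move together, and 0 members fell past the threshold. Medians were -0.08 in the alpha and 0.47 in the gamma cluster, but most members lie near background, so these values do not decide it. Shared probes stay open, as does an effect of Six2, which was not tested apart from them.

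For counts of calls, the 10 splits are likewise too few for a share under 0.05. In the mixed splits a real group difference also widens the spread within groups, which lowers their counts. Changed genes numbered 3068 in the real split and 0 in each of the others by limma (1085 at most at an unadjusted p under 0.05, against 6314), probe sets 6756 and 0 (13821 at most at an unadjusted p under 0.05, against 53648), lists 3 and 1, and diffSplice genes 2566 and 540.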

How the results depend on the processing

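Added after the data were seen were the chromosome settings, the bright and separate-variance probe set tests and the list without Cdh1. Cdh1 kept its direction and its call in all 17 alternatives, from -3.49 to -2.95; the subtraction of chromosome medians did not touch it, since its mean lies under 6. Six2 was higher in all 16 of its alternatives and passed with the mean of the probe sets (0.38), the brightest probe set (1.19) and dim rows left out (1.19). The replicate block, the variance trend and no moderation leave the differences of Six2 and Cdh1 as they were, so their direction is not tested there. The subtraction of chromosome medians left Six2 as it was too. For Six2, the settings with the brightest probe set and with dim rows left out rest on the same probe set. The count of changed genes was 4858 with the mean of the probe sets, 1119 at an adjusted p under 0.01 and 487 with a 2-fold limit. It was 1565 to 2447 when an array was left out, with 1691 and 1565 without control replicates 1 and 2 and 1951 and 1898 without Six2 replicates 1 and 2, where fewer arrays were tested. The probe set count was 13965 with dim rows left out and 0 to 1206 when an array was left out. With a replicate block, 1828 genes and 0 probe sets passed in limma (47403 probe sets at an unadjusted p under 0.05). The replicate numbers do not pair the arrays: deviations of same-numbered arrays correlated at -0.00635, -0.00842 and -0.0537, and no array correlated best with its own number.

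Lists called were 1 with dim rows left out, 0 with an estimated correlation, 30 with fry and 6 with chromosome medians subtracted. The adjusted p of the epithelial list was 0.0984 with dim rows left out, 0.464 with an estimated correlation, 0.0931 without chromosomes 1, 3 and 17 and 0.0684 without Cdh1. That of the keratins was 0.0599 with dim rows left out and 0.464 with an estimated correlation, and that of the cell cycle list 0.542 with an estimated correlation. Genes with unequal probe sets numbered 1019 among bright probe sets and 0 with separate variances. On simulated data the latter test made fewer false calls than diffSplice but recovered 60.5% of changed genes against 92.0%. Of 190 other named genes, 98 kept their call in every alternative run. Directions reversed with the brightest probe set for Dnmt3b (-0.34), Trp53inp1 (0.39), Fgfr1 (0.079), Klf2 (0.37) and Dhcr7 (0.15), with dim rows left out for Mmp16 (0.27) and Aldh1a1 (0.16), and with chromosome medians subtracted for Notch2 (-0.0087), Ccna2 (-0.012), Ndufb5 (-0.016) and Hspd1 (-0.019). Apart from left-out arrays, the cause was not tested. Dim genes lie near background, where RMA compresses folds.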

Other observations

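Genes of families that hold enzymes of xenobiotic metabolism were picked by symbol after their values were seen. The p-values here therefore describe the picked genes and do not test them. Some have other roles, such as the steroid enzymes Cyp11a1 and Cyp17a1. Of such genes, Aldh4a1, Aldh18a1 and the receptor Ahr are among the falls. Of 108, 2 rose and 24 fell, or 22.2% lower against 8.02% of all genes tested (Fisher's exact p = 3.75e-06 across genes, which are not independent replicates). Cyp1b1 (-2.73), Akr1c18 (-2.42), Aldh3a1 (-2.04), Gsta4 (-1.91) and Sult2b1 (-1.47) fell, as did the receptor Ahr (-0.78), while Tiparp (0.64) and Mgst2 (0.63) rose. The camera p was 0.000576 with the preset correlation and 0.0786 with an estimated correlation. Several of these belong to families of similar genes whose probes can match several members.

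The protocadherins that rose were 7 of 22 in the beta cluster and 7 of 21 in the gamma cluster, and 0 of 12 in the alpha cluster. Pcdhga1 rose by 1.57 (SE 0.18), Pcdhgb1 by 1.27 (SE 0.15) and Pcdhb20 by 1.07 (SE 0.17), from control levels of 3.84, 6.32 and 3.55. The camera p for the 55 members was 4.29e-06 with the preset correlation and 0.0214 with an estimated correlation. These genes too were chosen after their values were seen.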
